A study of Mus musculus with 2 samples.

How the data were processed

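Single-cell RNA sequencing was available for 2 mouse cultures of myeloid-derived suppressor cells, the immature myeloid cells that dampen T cell responses. Both cultures were differentiated in vitro with 40 ng/mL IL-6 and 40 ng/mL GM-CSF and harvested at day 4. One received the vehicle DMSO and the other 50 nM selinexor, a small-molecule inhibitor of the nuclear export receptor exportin 1. Per the labels' protocols, cells were tagged with feature barcodes, viable CD11b-positive cells were sorted, and the suspensions were pooled before droplet capture on the 10x Genomics platform. Each culture is called a library here, and each group holds 1 library.

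The deposited matrices hold raw UMI counts (unique molecular identifiers, counted molecules) per gene and cell, made by the authors with Cell Ranger 6.1.2, per the file headers and the submitters' processing notes, against genome build mm10, per the same notes. The annotation release and the rule by which the authors chose cell barcodes are not given in the sources used here. The feature tables list 32285 genes and 12 multiplexing tags. Tag counts were kept apart from gene counts and entered no gene total. Every barcode of the DMSO library had tag CMO305 as its most abundant tag and every barcode of the selinexor library had CMO306, and 0 barcodes occurred in both libraries. Gene coordinates were taken from a GENCODE annotation of the same build by matching Ensembl identifiers, and 143 of 143 looked-up genes matched.

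From these counts, cells with at least 200 detected genes and under 10% mitochondrial UMIs were kept, and doublets called by the Scrublet method in scanpy 1.11.5 were removed. This left 1739 DMSO and 1963 selinexor cells of 1784 and 1989 deposited barcodes. The mitochondrial limit removed 41 and 22 barcodes, among them the 3 and 7 under the gene minimum. The doublet caller marked 4 cells in each library, 0.216% of 3710 tested cells, so doublets were in effect not removed. The automatic threshold for the DMSO library moved with the numerical library settings at equal scores. The single-thread settings used throughout gave 4 calls and others gave 2, and the 2-call threshold was run as an alternative after this had been seen.

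Counts of kept cells were summed per library and scaled to CPM of the library's gene total. Log2 ratios are log2(CPM + 1) in the selinexor library minus the same in the DMSO library, which understates the ratio of genes with few counts. Summed counts have exact 95% Poisson intervals, ratios an exact conditional binomial interval and shares of cells a Clopper-Pearson interval. All cover counting error only. A gene with 0 UMIs in a library is given as a bound against a floor of 3 counts over that library or class.

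With 1 library per group there is no measure of the spread between cultures, so no test was run and no p-value or standard error is given. Genes with at least 50 UMIs over both libraries count as measured. Gene lists fixed before the data were examined (38 lists) were summarised by the median log2 ratio of their measured members and the number at least 1.5-fold higher or lower. Each median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The lists cover nuclear transport receptors with the Ran cycle, ERK feedback and immediate early targets, MAPK components, suppression genes, NADPH oxidase, granule and maturation genes of neutrophils, monocyte, macrophage and dendritic cell genes, MHC classes I and II, costimulation, targets of p53, NF-kB, STAT3 and STAT5, type I interferon response, S and G2M phase, ribosome biogenesis, integrated stress response, heat shock, glycolysis and hypoxia, cholesterol synthesis, apoptosis, chemokines, chemokine receptors, and other cell types (T, B, NK, erythroid, megakaryocyte, basophil, eosinophil, stem and stromal cells).

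Genes named in the text follow a rule also fixed before the data were examined. It takes 13 genes of interest, the 12 highest and 12 lowest ratios among genes with at least 100 UMIs and at least 20 CPM in 1 library, up to 4 members per list and the 6 highest and 6 lowest per compared class. The high and low genes had to keep their direction with every cell weighted equally, and mitochondrial, ribosomal protein, haemoglobin and unnamed genes were left out of them. Genes that lead a cluster are not given as results within it, and 1 list member that the rule names is not reported here.

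Cells of both libraries were clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, leidenalg 0.10.2). Clusters were named from 15 marker sets fixed before the data were examined, by a scoring set afterwards. A cluster took the class with the highest mean log2 ratio of its markers over the other cells, if at least 3 of them were 2-fold higher with at least 10 UMIs and no other class had more markers among the 10 leading genes. A cluster whose median UMI count was under 1/3 of its library's, with no marker of the class among those 10 genes, stayed unnamed. Classes with at least 100 cells in each library were compared by the same sums. These were the early and late neutrophil-like cells, and clusters 0 and 4, which have no name, were compared by number. Shares of cells with a Mki67 or Top2a UMI were taken after thinning each cell to 2000 UMIs.

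Alternatives covered other cell filters, TMM scaling (edgeR 4.0.16) and median-of-ratios scaling, equal weight per cell, thinning, removal of cells with Mki67 or Top2a, pseudocounts of 5 and 0.1, gene floors of 20 and 200 UMIs and other clustering settings, among them shares of cells from a clustering centred per library. Added after the data had been seen were the same cell mix in both libraries, over the clusters of the centred clustering with at least 20 cells in each library, which leaves out the dendritic cell-like cluster 10, removal of the low-UMI cluster, the higher doublet threshold, comparisons within the clusters of the centred clustering, and the stability runs. These repeated the clustering 20 times with another Leiden seed and 20 times with 4 random cells left out. A class left with under 20 cells in a library by an alternative gave no value, a limit also set afterwards.

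The steps were tested on simulated counts drawn from the mean profile and totals of the 2 libraries (10378 genes). Of 10181 unchanged genes, 95.8% had an interval that held the true value and 0 came out at least 2-fold apart. All 50 genes raised 4-fold and all 48 lowered to 0.25 of their level were recovered, with median log2 ratios of 1.97 and -1.85. At exactly 2-fold, on the edge of the limit, 26.0% of 50 raised and 40.8% of 49 lowered genes passed it. Random null lists fell outside percentiles 2.5 to 97.5 in 2.00% of 200 draws, and lists raised 1.5-fold lay above them in 100% of 50. The simulated genes were independent, with Poisson counts around 1 shared profile, so these values check the arithmetic only. They are no rate of false calls for real lists, whose members vary together between cells.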

Results

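Transcriptomes of single cells were collected from mouse myeloid-derived suppressor cell cultures grown with IL-6 and GM-CSF for 4 days, 1 with DMSO and 1 with 50 nM selinexor. The comparison asks how inhibition of exportin 1, which carries proteins with a leucine-rich export signal out of the nucleus, is reflected in the transcripts of these cells. After filtering, the DMSO library held 1739 cells with 14175475 UMIs and the selinexor library 1963 cells with 12784930 UMIs. The median cell had 7785 UMIs and 2106 genes in the DMSO library and 3908 UMIs and 1274 genes in the selinexor library. Mitochondrial UMIs made up a median of 2.27% and 2.37% per cell, ribosomal protein genes 15.9% and 16.1% of UMIs, and the 50 most abundant genes 36.8% and 36.0%. Each group held 1 library, so no difference has a replicate check, every value describes these libraries alone, and intervals cover counting error only.

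Xpo1, which encodes exportin 1 itself, was 2.99-fold higher in the selinexor library. It had 940 UMIs (66.3 CPM) in DMSO cells and 2558 UMIs (200.1 CPM) in selinexor cells, a log2 ratio of 1.58 (1.47 to 1.69). Xpo1 (ENSMUSG00000020290) lies on chromosome 11 of mm10, from 23256041 to 23298249 on the plus strand. Effector genes of myeloid suppression differed in opposite directions. Arg1, the arginase that depletes arginine, was lower (50 against 13 UMIs, log2 -1.17, but -2.66 with cells weighted equally and -0.53 after thinning). Nos2, the inducible nitric oxide synthase, had 59 UMIs in DMSO cells and 0 in selinexor cells, at least 17.7-fold lower against a floor of 3 counts. Cd274, the checkpoint ligand PD-L1, was higher (322 against 650 UMIs, log2 1.13).

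Among the other genes of interest, Dusp6, a phosphatase that switches off ERK, had a log2 ratio of 0.76 and the integrin Itgam, which encodes the sorted marker CD11b, 0.43. Ly6c2, high on monocytic cells, stood at 0.71, and at 0.19 with cells weighted equally, and Ly6g, a neutrophil surface marker, at -0.70 on 97 against 49 UMIs. Tgfb1, a suppressive cytokine, had 0.23 and Ptgs2, the inducible cyclooxygenase, 0.48 on 35 against 49 UMIs, or -0.07 without the low-UMI cluster. The p53 targets Cdkn1a and Mdm2 had -0.02 and 0.26. Il10 had 0 UMIs in both libraries and was not detectable at this depth.

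Ighm, the heavy chain of immunoglobulin M, had 194 UMIs in DMSO and 2936 in selinexor cells, a log2 ratio of 3.97 (3.78 to 4.18). It lies on chromosome 12 of mm10, from 113418558 to 113422730 on the minus strand. Also high in the selinexor library were Fn1, which encodes fibronectin (log2 2.95), Arrdc3, an arrestin-domain protein (2.90), Slc16a6, of the monocarboxylate transporter family (2.04), and Hmgn1, a nucleosome-binding protein (1.95). Fam122b (3.09), Tcaf1 (2.49) and the myelin protein gene Pmp22 (2.29) belonged to the same group. In selinexor cells, 6001 of 8670 Fn1, 296 of 397 Pmp22, 404 of 735 Fam122b and 2221 of 4047 Hmgn1 UMIs lay in cluster 3. That monocyte-like cluster had 393 selinexor and 7 DMSO cells. It held smaller parts of Ighm (1184 of 2936), Slc16a6 (956 of 2524) and Arrdc3 (186 of 522), and cluster 4 held 164 of 358 Tcaf1 UMIs. The chemokine genes Ccl5 (3.99) and Ccl22 (3.50), the actin bundler Fscn1 (3.34) and the lymph node homing receptor Ccr7 (3.24) completed the 12 highest. Their UMIs came from few cells: the 34 selinexor cells of cluster 10, a dendritic cell-like cluster, held 1466 of 1491 Ccl5, 2479 of 2547 Ccl22, 463 of 474 Fscn1 and 563 of 570 Ccr7 UMIs. The same cell mix in both libraries leaves that cluster out, so the values it gives, -1.31 for Ccl5, -0.04 for Ccl22, -1.16 for Ccr7 and 0.0037 for Fscn1, are those of the remaining cells.

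The genes lowest in the selinexor library included Cxcl2, a neutrophil-attracting chemokine, with 8985 against 2045 UMIs (log2 -1.98, -2.05 to -1.91). The complement genes C1qa (-2.83), C1qc (-2.11) and C1qb (-2.06), the platelet factor Pf4 (-2.66) and the lectin receptor Asgr2 (-2.04) were low together. In DMSO cells, 420 of 433 C1qa UMIs, 397 of 454 Pf4 UMIs and 419 of 456 Asgr2 UMIs lay in the macrophage-like cluster 7, which the dendritic cell markers H2-Ab1 and H2-Eb1 lead beside the C1q genes. The surface antigen gene Ly6a (-2.68) and Dmkn (-2.41) were lower as well. The stefin A family members Cstdc4 (-2.31), Csta2 (-2.18) and Cstdc5 (-2.18) were lower, but near-identical copies share reads and the value of each is uncertain. The unnamed cluster 6, with 322 DMSO and 10 selinexor cells, held 678 of 1356 Dmkn, 27690 of 63977 Cstdc4 and 6894 of 14666 Csta2 DMSO UMIs. Cstdc5 had most in cluster 5 (12405 of 32702) and Ly6a in cluster 7 (637 of 997). Mcpt8, a basophil protease, stood at -3.84, and 214 of its 301 DMSO UMIs came from 1 cell.

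Of 10390 measured genes, 205 were at least 2-fold higher and 114 at least 2-fold lower in the selinexor library, 64.3% higher among them. The median log2 ratio of all genes was 0.13. TMM scaling shifted it by -0.12 and median-of-ratios scaling by -0.14, which gave 148 higher and 170 lower genes (46.5% higher) and 143 higher and 176 lower (44.8%). With the same cell mix, 129 were higher and 127 lower.

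**Figure D1:**
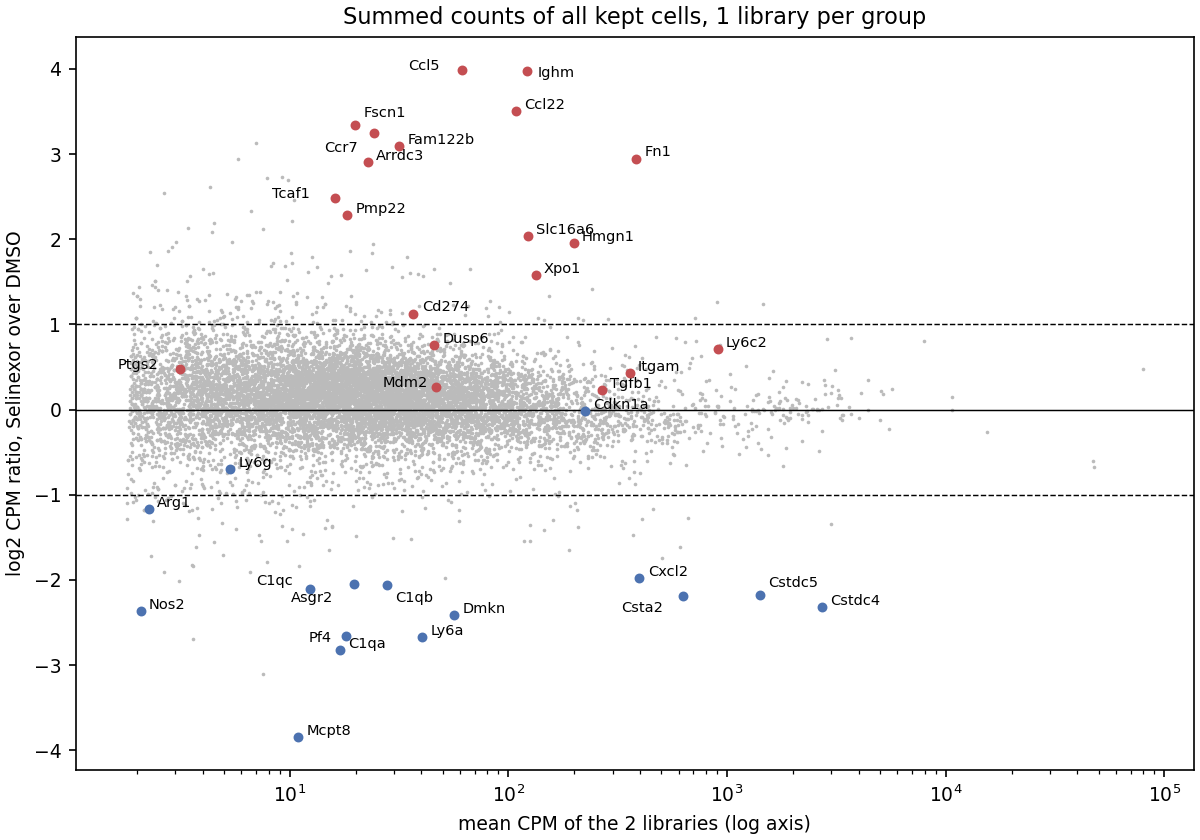
Log2 ratio of summed CPM + 1 in the selinexor over the DMSO library (vertical axis) against the mean CPM of the 2 libraries (log axis), 1 point per measured gene, with named genes in red above 0 and blue below 0 and dashed lines at 2-fold. Ighm (3.97) and Xpo1 (1.58) lie above the upper line and Cxcl2 (-1.98) below the lower one. Nos2, with 0 selinexor UMIs, is drawn at its value with the pseudocount, which is no bound.

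Interferon-stimulated genes were low as a group in the selinexor library. Of 16 measured members of the type I interferon response, 9 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -1.28, below all 10000 matched random lists. Among them were the ubiquitin-like Isg15 (-1.91), Rtp4 (-1.82), the transcription factor Irf7 (-1.79) and the RNA-binding Ifit1 (-1.72). Their counts were low, with 156 against 28 UMIs for Isg15, and with a floor of 200 UMIs 3 members were lower and after thinning 4.

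Primary granule genes, which encode the proteases and peroxidase made by promyelocytes, had a median of -1.08, also below all random lists, with 5 of 8 lower and 0 higher. Ctsg stood at -1.55, Mpo at -1.51, Prtn3 at -1.47 and Elane at -1.17. The share of early neutrophil-like cells, whose markers these are, was 11.8% of DMSO and 6.67% of selinexor cells, and without cells holding Mki67 or Top2a 3 members were lower, with Mpo at -0.19 and Elane at -0.14. Specific granule genes had a median of -0.24 (percentile 1.09), with 2 of 13 lower, the transcription factor Cebpe (-0.82) and the antimicrobial Pglyrp1 (-0.60), and a median of 0.03 after thinning and percentile 10.8 without cells holding Mki67 or Top2a. The late maturation list had 7 lower and 4 higher of 20 members and a median of -0.21 (percentile 0.10). The decoy receptor Il1r2 stood at -1.10, Trem3 at -1.03 and the chemokine Ccl6 at 0.83, while Stfa2l1 (-1.28) is uncertain for its near-identical copies, and with cells weighted equally the median was 0.14.

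Genes of glycolysis and hypoxia and of the ATF4 response were low in the selinexor library. The glycolysis and hypoxia list had 8 of 22 members lower and 0 higher, 20 of them below 0, with a median of -0.45, below all random lists. Egln3, an oxygen-sensing prolyl hydroxylase, stood at -1.98, the mitophagy gene Bnip3 at -1.31, the glycolytic enzyme Tpi1 at -0.75 and the glucose transporter Slc2a1 at -0.72. The list of ATF4 and the integrated stress response had 8 of 16 lower and a median of -0.38, below all random lists, with the asparagine synthetase Asns at -0.87 and the transcription factor Atf3 at -0.83. Without cells holding Mki67 or Top2a its median was 0.16, and after thinning it stood at percentile 12.5. Cholesterol biosynthesis had a median of -0.14 (percentile 0.37) and 1 of 17 lower, the farnesyl diphosphate synthase Fdps (-0.97), but -0.06 (percentile 2.86) with at least 1000 genes and under 5% mitochondrial UMIs per cell.

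All 7 MHC class II members lay below 0, with a median of -0.44 (percentile 0.105) and 1 at least 1.5-fold lower, the beta chain H2-Ab1 (-0.67). Without cells holding Mki67 or Top2a the median was -0.13 (percentile 14.5). The class II transactivator Ciita had -0.49. H2-Ab1 and H2-Eb1 are leading genes of the macrophage-like cluster 7, which held 12.2% of DMSO and 2.65% of selinexor cells. MHC class I had 8 of 13 members below 0 and 5 above and a median of -0.17 (percentile 1.83), whose counting interval of -0.22 to 0.03 includes 0, with the immunoproteasome subunits Psmb8 (-0.73) and Psmb9 (-0.69) lower and H2-Q7 (0.82) higher on 26 against 51 UMIs. Its median was 0.15 with cells weighted equally, it stood at percentiles 8.35 without cells holding Mki67 or Top2a and 2.83 with a floor of 200 UMIs, and H2-Q7 was -0.37 with the same cell mix, which leaves out cells with 39 of its 51 selinexor UMIs.

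The G2M list had a median of -0.21, below all random lists, with 4 of 50 lower and 0 higher, among them the mitotic ubiquitin-conjugating enzyme Ube2c (-0.80) and the kinetochore gene Cenpf (-0.62). Its median was 0.24 without cells holding Mki67 or Top2a, which are themselves proliferation genes. Chemokines and cytokines had 6 higher and 5 lower of 19 and a median of -0.16 (percentile 0.31), with Cxcl3 at -1.65 beside the values of Cxcl2, Ccl5 and Ccl22, and 0.02 with a floor of 200 UMIs. Basophil and mast cell genes had 3 measured members and a median of -2.69, below all random lists, with the growth factor receptor Kit at 0.81. The low values rest on few cells. The 99 DMSO UMIs of the protease Prss34 came from 3 cells, with 51 in 1 cell, and 98 of them lay in cluster 9.

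The medians of 4 lists lay above percentile 97.5, and each lay below it under at least 1 other setting. Monocyte genes had 9 of 21 members higher and 3 lower and a median of 0.46, above all random lists, with Fn1, the transcription factor Irf8 (1.22) and the ribonuclease Ear2 (1.22) higher and Ms4a6c (-1.52) lower. With cells weighted equally the monocyte median was 0.19 (percentile 88.4), and without cells holding Mki67 or Top2a 0.23 (percentile 95.1). Karyopherins and the Ran cycle, the nuclear transport machinery to which Xpo1 belongs, had 4 of 27 higher, 1 lower and a median of 0.35 (percentile 99.8). The importin Kpna4 stood at 0.76 and the exportin Xpo6 at 0.67. The importin Kpna2 was at -0.76 and at 0.23 without cells holding Mki67 or Top2a, where the list stood at percentile 95.03, and with cells weighted equally the list median was 0.19 (percentile 72.8). MAPK pathway components had 2 of 19 higher, 0 lower and a median of 0.32 (percentile 99.3), with the kinase Mapk8 at 0.69, but 0.26 (percentile 96.4) after thinning and percentile 97.2 with cells weighted equally. Chemokine receptors and adhesion genes had 3 of 14 higher and 1 lower and a median of 0.28 (percentile 99.1), with the integrin Itga4 at 0.97, the tetraspanin Cd9 at 0.84 and the neutrophil receptor Cxcr2 at -0.60, or -0.03 with cells weighted equally. With at least 1000 genes and under 5% mitochondrial UMIs per cell Cxcr2 stood at -1.24 and the list median was 0.18 (percentile 92.2), and after thinning, with the same cell mix and without the low-UMI cluster it lay at percentiles 93.8, 96.6 and 93.3.

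The medians of 16 lists lay between percentiles 2.5 and 97.5, but 11 of them lay outside under at least 1 other setting. ERK feedback and immediate early targets had a median of 0.08 (percentile 29.7), with 1 of 17 higher and 2 lower, the transcription factors Egr1 at -1.18 on 1168 against 459 UMIs and Fosl1 at -1.03. Myeloid suppression genes had -0.04 (10.1), with 3 of 26 higher and 6 lower, the cytokine Il1b at -0.79. Nos2 lies below this median at its bound as well. NADPH oxidase had -0.04 (53.5), with the catalytic subunit Cybb at 0.76 and Ncf4 at -0.62. Macrophage genes had -0.02 (23.2), with 6 of 21 higher and 7 lower and Gpnmb at 1.65, and dendritic cell genes 0.03 (20.6), with 5 of 13 higher and 3 lower and the chemokine Ccl17 at -1.54.

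Costimulation genes had 0.40 (94.7), with 2 of 8 higher and Cd80, a ligand of CD28, at 1.00. Targets of p53 had 0.20 (74.1), with 4 of 23 higher and 0 lower, the pro-apoptotic Pmaip1 at 1.15. NF-kB targets had 0.21 (90.1), with 4 of 20 higher and 3 lower, the apoptosis inhibitor Birc3 at 0.79. STAT3 targets had 0.05 (43.8), with the kinase Pim1 at 0.85, and STAT5 targets -0.02 (24.4), with the receptor antagonist Il1rn at 0.85 and the cyclin Ccnd2 at 0.79, or 0.06 with cells weighted equally. The S phase list had 0.10 (30.02), ribosome biogenesis 0.05 (21.9), heat shock 0.14 (81.1) and apoptosis regulators 0.14 (62.5). With the same cell mix, suppression genes lay at percentile 0.32, macrophage genes at 0.06, NF-kB targets at 2.17, STAT5 targets at 1.26 and S phase genes at 99.78. With cells weighted equally, NF-kB targets lay at 98.7 and S phase and ribosome biogenesis genes at 0.07, and without cells holding Mki67 or Top2a the ERK list lay at 0.455. STAT3 targets lay at 0.15 without the low-UMI cluster and dendritic cell genes at 99.7 with a floor of 200 UMIs, so no direction is read for these lists.

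Markers of other cell types were sparse. Of the B and plasma cell list 3 genes were measured, with a median of 0.21 (percentile 69.9). Beside Ighm, the B cell receptor gene Cd79b had 50 against 28 UMIs and the transcription factor Ebf1 25 against 28. The stem and progenitor list had 5 measured members and a median of 0.31 (79.3), with the transcription factor Sox4 at 2.22. With floors of 20 and 200 UMIs the B cell list lay at percentile 0.755 and the stem cell list at 98.6. No T cell or NK cell gene was measured, and the remaining lists had under 3 measured members. These were the erythroid Car2 (0.39, but -0.92 with the same cell mix, which leaves out 197 of its 307 selinexor UMIs), the megakaryocyte Pf4, the eosinophil Ear6 (1.64) and Siglecf (0.11, but -0.54 without the low-UMI cluster), and the endothelial Pecam1 (-1.46).

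**Figure D2:**
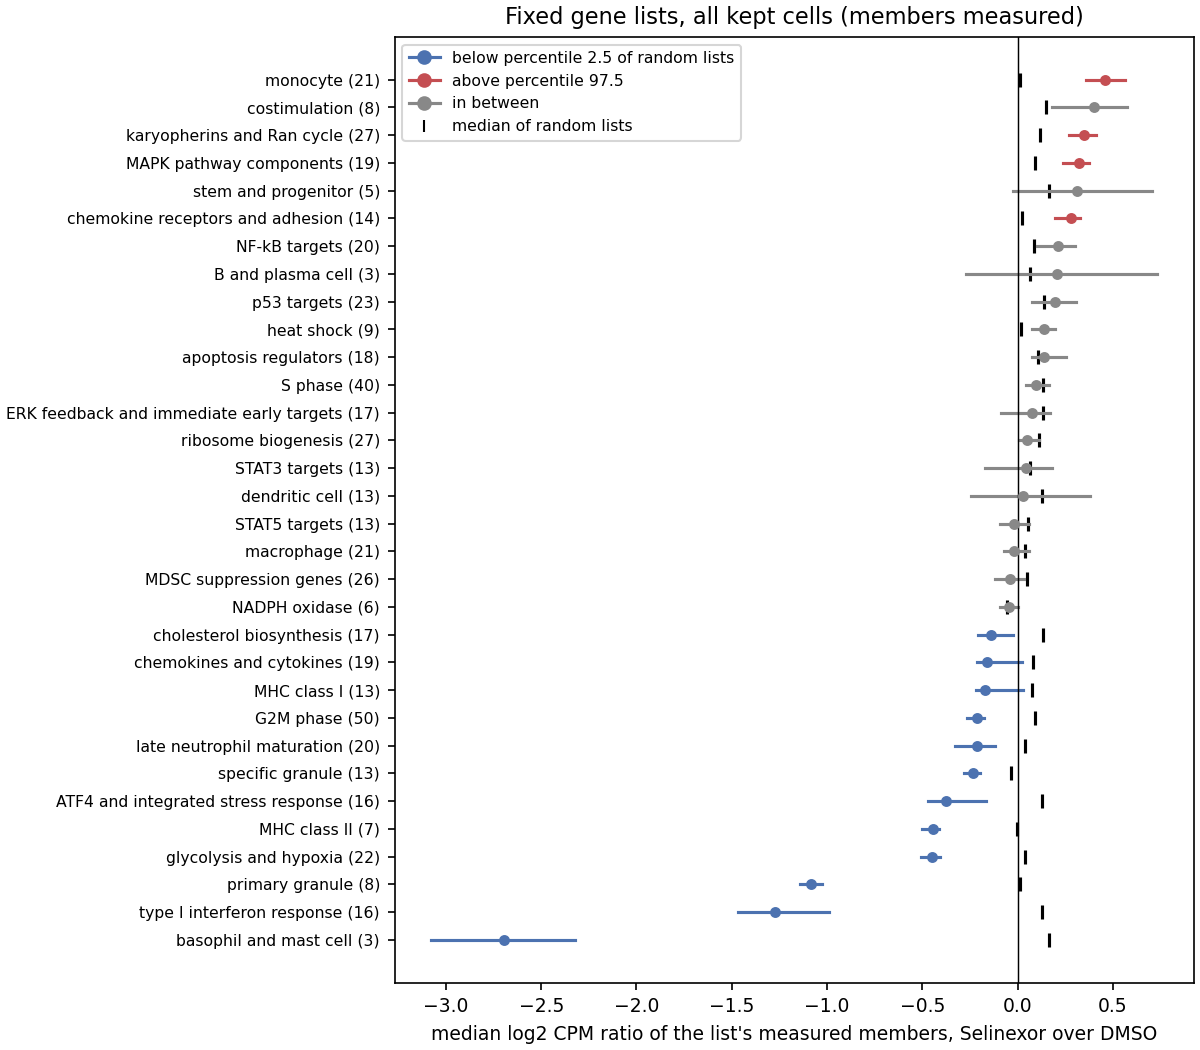
Median log2 ratio of each fixed list in the selinexor over the DMSO library (horizontal axis), with the number of measured members in parentheses. Bars are 95% intervals from Poisson draws of the counts and black ticks the median of 10000 matched random lists. Lists below percentile 2.5 (blue) run from basophil and mast cell genes (-2.69) to cholesterol biosynthesis (-0.14), and 4 lists lie above percentile 97.5 (red).

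The libraries differed in which cells were recovered after the CD11b sort. Joint clustering gave 11 clusters, and most held mainly cells of 1 library. The unnamed cluster 6, led by Csta3 and Dmkn, held 18.5% of DMSO and 0.509% of selinexor cells. In the clustering centred per library a cluster led by the same 2 genes held 16.6% and 3.97%. Of its cells, 286 of 288 DMSO but 9 of 78 selinexor ones lay in cluster 6. Another 63 of the selinexor cells lay in the monocyte-like cluster 3, so the 3.97% is mostly other cells. Early neutrophil-like cells made up 11.8% (10.3 to 13.4) of DMSO and 6.67% (5.61 to 7.87) of selinexor cells. The early, intermediate and late neutrophil-like cells together made up 48.4% (46.0 to 50.7) and 29.4% (27.4 to 31.5). The monocyte-like cluster 3, led by the monocyte marker Fn1 and the macrophage marker Mrc1 alike, held 0.403% and 20.02%, the macrophage-like cluster 7 12.2% and 2.65% and the dendritic cell-like cluster 10 0.230% and 1.73%. A cluster held almost wholly by 1 library cannot be told from that library, and these shares moved with the clustering. At resolution 2.0 the classes held 2.24% and 16.9%, 8.34% and 0.204%, and 4.31% and 3.72%, the clustering centred per library gave a monocyte-like share of 10.7% and 17.9%, and thinning a macrophage-like one of 5.33% and 14.8%. At resolution 2.0 and in the centred clustering a cluster led by C1qa and Asgr2 was named dendritic cell-like. The order of the libraries thus turned for the dendritic cell-like class. For the macrophage-like class it turned only after thinning, where no class was named monocyte-like, so that turn may be one of names. The centred clustering named no macrophage-like class, and no order is read for either class. Cluster 0, with medians of 1042 UMIs and 0.870% mitochondrial UMIs per cell, held 8.28% of DMSO and 36.0% of selinexor cells. Its highest score was for late neutrophil markers, with 6 of 10 at least 2-fold higher, and only the depth rule left it unnamed. The nearest cluster in the centred clustering held 16.8% and 32.9%. Of its 293 DMSO cells, 142 lay in cluster 0 and 147 in the late neutrophil-like cluster 1. Of its 646 selinexor cells, 639 lay in cluster 0 and 6 in cluster 1. The basophil genes Mcpt8 and Prss34 led that centred cluster. Over the DMSO library, however, 3 cells held all 99 Prss34 UMIs and 1 cell held 214 of 301 Mcpt8 UMIs. In runs with another seed, up to 12.3% of DMSO cells lay in cluster 0. With it the neutrophil-like share was 56.6% and 65.4%, so the order of the libraries depends on that cluster. Primary granule genes, the markers of the early class, were lower within it (median -0.76), and the shares are therefore not clean numbers of cells. At resolution 2.0, 100 of the 205 DMSO and 48 of the 131 selinexor cells of the early class lay in a cluster led by Ctsg and Mpo. Another 105 and 83 lay in an intermediate neutrophil-like cluster, so the class does not hold the same mix of cells in both libraries. In 20 runs with another seed the early share stayed between 11.6% and 11.8% in DMSO and between 6.42% and 7.18% in selinexor cells, but at resolution 2.0 it was 5.75% and 2.60%.

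Xpo1 was higher in the selinexor cells of every class and cluster compared. Its log2 ratio was 1.08 (0.76 to 1.40) in early neutrophil-like cells, 2.14 (1.80 to 2.48) in late ones, 1.96 (1.13 to 2.91) in cluster 0 and 0.94 (0.74 to 1.15) in cluster 4, which was led by mitotic genes. Ighm and Slc16a6 were at least 2-fold higher in all 4, and Cxcl2 at least 2-fold lower. These were the only such genes of 2676 measured in all 4. The log2 ratio of Ighm was 1.53, 6.58 and 2.83 in early, late and cluster 4 cells, and in cluster 0 it was at least 14.5-fold higher, with 0 against 216 UMIs. Slc16a6 (chromosome 11, from 109450855 to 109473598 on the minus strand) had 1.15, 2.25, 2.70 and 1.84. Cxcl2 (chromosome 5, from 90903871 to 90905938 on the plus strand) had -1.42, -2.30, -4.36 and -2.02, but 0.16 in the early class formed at resolution 2.0.

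The glycolysis and hypoxia list was low in each. Its median was -0.47 in early cells (8 of 22 lower), -0.62 in late cells (13 of 21), -0.77 in cluster 0 (10 of 14) and -0.44 in cluster 4 (6 of 20), below percentile 0.01 or at it. Tpi1 had -1.07, -1.13, -1.15 and -0.63, and Bnip3 -1.89, -0.97, -0.16 and -1.32. Egr1 stood at -0.79, -1.06, -1.64 and -1.21 and Dusp6 at 0.97, 1.09, 0.29 and 0.71. The cell cycle inhibitor Cdkn1a went both ways, with 0.80 in early and -1.07 in late cells.

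In early neutrophil-like cells, with medians of 11431 and 11679 UMIs, the acute-phase gene Saa3 (1.78), the chemokine Ccl6 (1.67), the matrix protein gene Thbs1 (1.58) and the neutrophil collagenase Mmp8 (1.56, but 0.04 at resolution 2.0) were higher in the selinexor library. Chchd10, a mitochondrial protein (-1.82), and the adenosine deaminase Ada (-1.45) were lower. Targets of p53 had a median of 0.51 (5 of 10 higher, 0 lower) and monocyte genes 0.86 (6 of 9 higher, 1 lower), each above all random lists. Chemokine receptors and adhesion genes had 0.52 (4 of 11 higher, 0 lower). The uneven split of this class at resolution 2.0, given with the shares of cells, limits these values as well.

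In late neutrophil-like cells, with medians of 3445 and 3328 UMIs, Fam122b (3.50), Arrdc3 (3.18), the ficolin Fcnb (3.05), the antiproliferative Btg3 (2.58) and Gpnmb (2.53) were higher. The tautomerase Ddt (-3.98), the adaptor Scimp (-3.03), the argininosuccinate synthase Ass1 (-2.89), the adaptor Dok2 (-2.47) and E-cadherin, Cdh1 (-2.41), were lower. In the class from the clustering centred per library Fcnb stood at 2.02, Ddt at -1.97 and Scimp at -1.996. Ribosome biogenesis genes had a median of -0.95 (13 of 14 lower, below all random lists), interferon genes -1.09 (8 of 10 lower, percentile 0.02), MHC class I genes -0.68 (6 of 9 lower, percentile 0.21) and STAT5 targets -0.53 (6 of 13 lower, 1 higher). The STAT5 median was -0.17 (percentile 9.91) in the class from the clustering centred per library, and with cells weighted equally it was -0.36 (percentile 10.2) and that of MHC class I -0.44 (percentile 7.66). Specific granule genes had 0.47 (6 of 13 higher), but -0.44 at resolution 2.0. Cluster 1 held 432 of the 534 DMSO cells of this class and cluster 2 held 308 of the 355 selinexor cells, so the late class compares largely different clusters.

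In cluster 0, with medians of 1035 and 1046 UMIs, the transcription factor gene Foxn3 (2.91, 3 against 117 UMIs), Oga, which removes O-GlcNAc (2.04), and Spen (2.01) were higher. The lipoprotein lipase Lpl (-2.94), osteopontin, Spp1 (-2.83), and the annexin Anxa1 (-1.998) were lower. Macrophage genes had a median of -1.04 (8 of 11 lower) and chemokines and cytokines -1.34 (6 of 9 lower). At resolution 2.0, 79 of the 144 DMSO and 633 of the 706 selinexor cells of cluster 0 lay in the same cluster. A cluster led by Ccl4, Gadd45b and Cxcl2 took 23 and 25 cells, and another led by Egr3 took 42 and 8. The values in cluster 0, those of Cxcl2 and Egr1 included, therefore compare partly different cells.

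In cluster 4, with medians of 15329 and 15546 UMIs, Tcaf1 (3.26), Fn1 (2.53), the ubiquitin ligase Nedd4 (2.40), the serpin Serpinb6a (2.38) and Fam122b (2.31) were higher. Ly6a (-3.42) was lower, and so were the stefin A genes Cstdc5 (-4.19), Stfa2 (-4.17), Cstdc4 (-3.89), Stfa2l1 (-3.73) and Stfa1 (-3.49), uncertain as near-identical copies. MHC class II genes had a median of -2.07 (5 of 6 lower), with H2-Ab1 at -2.73 and H2-Eb1 at -2.14. Karyopherins had 0.38 (5 of 26 higher, 1 lower). At resolution 2.0, 152 of the 190 DMSO cells of cluster 4 lay in a cluster led by histone genes and 112 of the 167 selinexor cells in another led by Anln, so these values, MHC class II included, compare largely different cells.

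**Figure D3:**
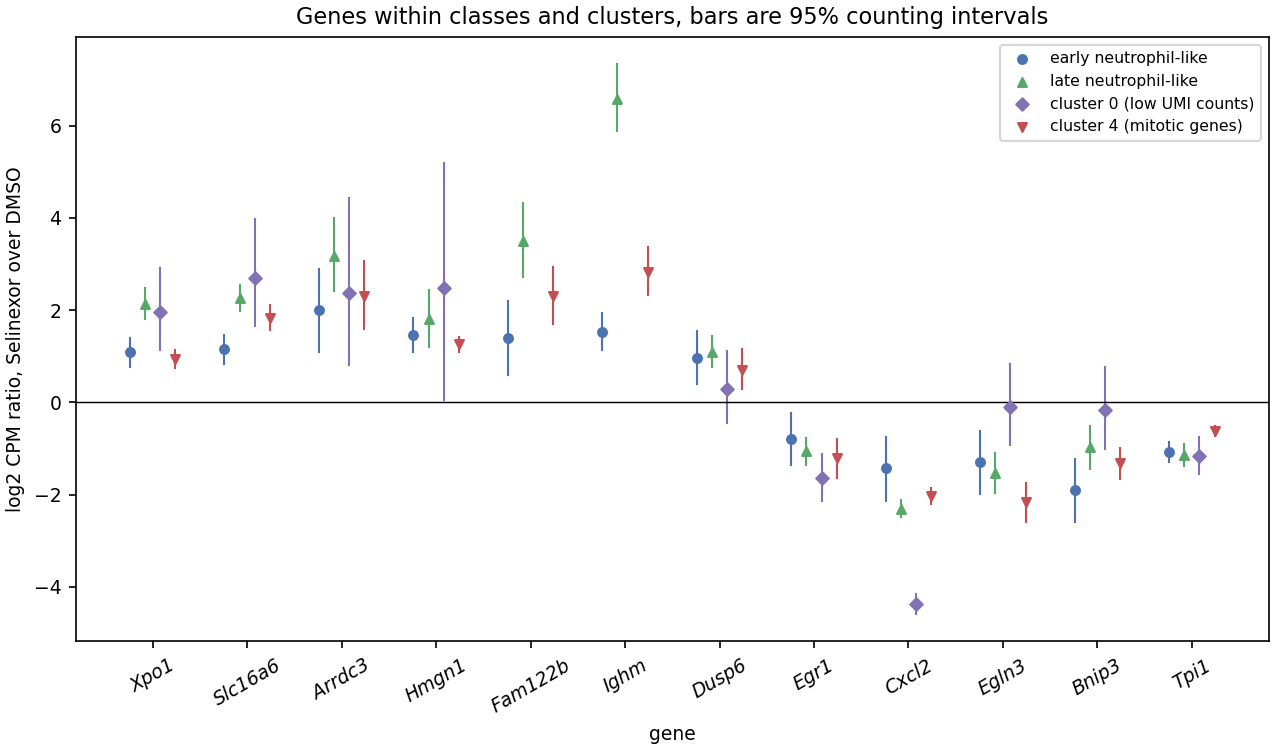
Log2 CPM ratio of 12 genes in the selinexor over the DMSO library (vertical axis) within early and late neutrophil-like cells, cluster 0 and cluster 4, with 95% counting intervals as bars. Xpo1 lies between 0.94 and 2.14 and Cxcl2 between -4.36 and -1.42. Ighm in cluster 0, with 0 DMSO UMIs, and Fam122b in cluster 0, with too few UMIs, are not drawn.

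Among cells with at least 2000 UMIs, shares with a proliferation transcript overlapped within counting error when cells were thinned to the same depth. After thinning to 2000 UMIs, Mki67, a marker of dividing cells, or Top2a, a topoisomerase of dividing cells, had a UMI in 466 of 1425 DMSO cells (32.7%, 30.3 to 35.2) and 410 of 1180 selinexor cells (34.7%, 32.0 to 37.5). Thinning left out 314 and 783 cells. Without it the shares were 40.9% and 36.6% at medians of 7785 and 3908 UMIs. In late neutrophil-like cells, which should lack both genes, the share was 4.53% (2.66 to 7.16) and 13.1% (9.41 to 17.6), a class that is mostly cluster 1 in DMSO and cluster 2 in selinexor cells. In cluster 4, led by mitotic genes, it went the other way, with 89.9% (84.7 to 93.8) and 78.4% (71.4 to 84.4). S phase genes took 0.159% and 0.168% of all UMIs and G2M genes 0.559% and 0.490%. When thinned to 1000 UMIs the shares were 21.2% and 18.6%, the opposite order, so no order is read from them.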

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

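These values come from multiplexing tags, which entered no comparison, and no test was run on them. Tag CMO303 had a median of 36 UMIs per cell in the DMSO and 40 in the selinexor library, and tag CMO304 had 28 and 31. Each library also held the other's tag, with 43 UMIs per cell of CMO305 in the selinexor library and 48 of CMO306 in the DMSO library. The libraries' own tags had medians of 976 and 1355, and the protocols in the labels say that tagged suspensions were pooled before capture.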

How the results depend on the processing

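The alternatives with the same cell mix, without the low-UMI cluster, with the higher doublet threshold and with classes from the centred clustering, and the stability runs, were chosen after seeing the data. No paired analysis was possible because each group holds 1 library, with replicate number 1 in both. A turn of sign was counted for genes at least 1.5-fold apart with a counting interval off 0 and for lists outside percentiles 2.5 to 97.5. Of 353 results, 21 turned at least once and 332 did not, results near 0 included. Over all alternatives 2294 values stayed within their counting interval or within 1.5 times the main count, 764 moved beyond it and 22 turned sign. Pseudocounts aside, 61 of 141 genes over all cells and 13 of 52 values of genes within classes turned sign or moved by over 1.5-fold under at least 1 alternative, results near 0 included, and 80 and 39 did not. Among those nearer 0 were Il1r2 (-0.29), Egln3 (-1.03), Bnip3 (-0.71), Rtp4 (-1.09) and Gpnmb (0.91) with cells weighted equally, Ctsg (-0.66), Ccl17 (-0.82) and Tcaf1 (1.72) without cells holding Mki67 or Top2a, and Cxcl3 (-0.76) and Ms4a6c (-0.93) after thinning. Xpo1 kept a log2 ratio between 1.43 and 2.10 over all cells. The low UMI counts of Arg1, Nos2, Ptgs2 and the interferon genes limit what can be said of them, and the shallower selinexor cells limit shares of cells.

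Pseudocounts set how far genes with few counts move, and 5 gave 76 genes higher and 50 lower, while 0.1 gave 319 higher. With a floor of 200 UMIs, which measures fewer genes, 113 were higher and 73 lower, 3 interferon genes were lower, and the chemokine median was 0.0207. Median-of-ratios scaling gave 176 lower genes and Xpo1 at 1.43, and TMM gave Xpo1 at 1.45, both by their constant shift. The same cell mix leaves out small clusters, the dendritic cell-like cluster 10 among them, and with them 1466 of 1491 Ccl5, 2479 of 2547 Ccl22, 563 of 570 Ccr7, 39 of 51 H2-Q7, 40 of 49 Cd40 and 289 of 600 Socs2 UMIs of the selinexor library. It gave 129 higher genes and Xpo1 at 1.47, for which the cause was not tested, and Ccl5 at -1.31, Ccl22 at -0.0403, Ccr7 at -1.16, H2-Q7 at -0.37, Cd40 at -0.44 and Socs2 at -0.0419.

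The cause was not tested for the following values. With cells weighted equally 175 genes were lower, Xpo1 stood at 1.80, Chac1 at 0.29, the late neutrophil median at 0.14 and the MHC class I median at 0.15. Without cells holding Mki67 or Top2a, Xpo1 stood at 2.10, Kpna2 at 0.23, Nusap1 at 0.92 and Cdk1 at 0.47, 3 primary granule genes were lower, and the medians of G2M and ATF4 were 0.24 and 0.16. Thinning to 2000 UMIs gave a specific granule median of 0.0259, 4 lower interferon genes, early neutrophil-like shares of 6.11% and 3.56% and shares of all stages of 40.1% and 22.6%.

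Resolution 2.0 gave early shares of 5.75% and 2.60%, 32.0% of selinexor cells in all stages, early-class values of 0.16 for Cxcl2, -0.0194 for MAPK components and 1.69 for chemokines, and a late-class specific granule median of -0.44. Resolution 0.5 put 43.0% of DMSO cells in all stages, and all deposited barcodes 42.0%. With 15 principal components the early shares were 6.96% and 4.02% and the DMSO share of all stages 52.1%. The clustering centred per library gave 40.7% and 32.2% for all stages and late-class medians of -0.10 for specific granule genes and 0.19 for chemokines. Thinned to 1000 UMIs, cells with Mki67 or Top2a made up 21.2% and 18.6%.

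Leaving out 4 random cells gave 11 to 13 clusters with an adjusted Rand index of 0.864 to 0.959 to the clustering used. The low-UMI cluster stayed unnamed in 17 of 20 of these runs, and intermediate neutrophil-like cells reached 100 cells per library in 7 of 20. Without cells holding Mki67 or Top2a, too few early and cluster 4 cells were left for a value.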

Other observations

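The comparisons within the centred clustering, the B-lineage and free RNA tests on Ighm and the marker test on the low-UMI cluster were chosen only after the result was seen. In the clustering centred per library, cluster 2, led by Pf4 and Mrc1 with the monocyte marker Fn1, held 186 DMSO and 352 selinexor cells. Of these, 150 DMSO cells lay in the macrophage-like cluster 7 of the joint clustering and 327 selinexor cells in its monocyte-like cluster 3, so the values within it compare largely different clusters. Among its genes, Ighm (log2 4.21), Fam122b (3.51), Trim6 (3.30), Arrdc3 (2.88) and Slc16a6 (2.70) were higher in selinexor cells. Ly6a (-3.78), the transcription factor Maf (-3.54), Egln3 (-3.20), the costimulatory receptor Tnfrsf9 (-2.82) and the arginase Arg1 (-2.62) were lower. All 7 MHC class II genes lay below 0, with 6 at least 1.5-fold lower and a median of -1.41. Macrophage genes had a median of -0.66 (11 of 20 lower, 2 higher) and NF-kB targets -0.43 (7 of 19 lower, 0 higher). S phase genes had 0.31 (9 of 35 higher, 1 lower) and karyopherins 0.35 (5 of 25 higher, 0 lower).

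Xpo1 was higher in selinexor cells, and a change in cell mix or the scaling could in principle raise it. Median-of-ratios and TMM scaling left 1.43 and 1.45 of the observed 1.58, which argues against scaling as the whole cause. The DMSO cells' own cluster profiles were reweighted to the selinexor cell mix, with small clusters left out. They gave a log2 ratio of 0.0681 from the centred clustering and 0.0853 from the clusters used in the report. Neither value can weigh the selinexor share of cluster 3. The centred cluster 2 joins mostly cluster 7 DMSO cells with mostly cluster 3 selinexor cells. Cluster 3 itself, with 1030 of 2558 selinexor Xpo1 UMIs, had 7 DMSO cells, too few for a profile. The bound written beforehand, a ratio of at least 1 in every cluster, was missed: 8 of 10 compared groups reached it, and cluster 4 (0.94) and its counterpart in the centred clustering (0.92) did not. The 10 groups, 4 of the joint and 6 of the centred clustering, share cells, so they are not 10 separate checks. The lowest counting limit within a compared group was 0.72, which argues against the cell mix as the whole cause in those groups. This criterion was set after the result was seen, and some of the groups compare largely different clusters. An effect of exportin 1 inhibition on its own transcript is a hypothesis that stays open and untested, because treatment and library cannot be told apart with 1 library each.

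Ighm was higher in the selinexor cells of all 4 classes and clusters compared, and B-lineage cells, free RNA or the cell mix could bring such counts. In the 947 selinexor cells with an Ighm UMI, 5 other B-lineage genes had 30 UMIs beside 2936 of Ighm, or 1.02% (upper limit 1.46%), and the sort for live CD11b-positive cells would remove most B cells. Free RNA would give like counts per cell at like depth. Selinexor cells of cluster 3 (median 11605 UMIs) had 3.01 and those of cluster 10 (10866) 0.118 Ighm UMIs per cell. That ratio of 25.6 rests on 4 UMIs in 34 cells, and it was 2.86 between clusters of at least 100 cells. Per the protocols the suspensions were pooled before capture, where free RNA would reach both libraries alike. In cluster 0, 144 DMSO cells (median 1035 UMIs) had 0 Ighm UMIs and 706 selinexor cells (1046) had 216. In cluster 4, 190 DMSO cells had 31 and 167 selinexor cells 220. These counts argue against free RNA from a pooled capture as the whole cause. The mix-only log2 ratio was -0.0188 (0.113 from the clusters used in the report) against 3.97, with the same limits as for Xpo1. Cluster 3, with 7 DMSO cells, held 1184 of the 2936 selinexor Ighm UMIs, so these values cannot weigh its part. An effect of the treatment and any other difference between the libraries stay open and were not tested.

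The cluster of low UMI counts held more of the selinexor library, and droplets that hold free RNA or no whole cell might form it. Markers of other classes stood at a median of 0.131 of their level in the whole selinexor library (42 markers), where free RNA alone would keep them near that level. The cells' own tag had a median of 1616 UMIs per cell against 1129 in other selinexor cells, a ratio of 1.43, where droplets without a whole cell would carry less. Every deposited selinexor barcode had this tag as its most abundant one. Droplets with little of it may thus be missing, so the ratio cannot decide the question. Viable cells had been sorted, and the cluster had a median of 0.870% mitochondrial UMIs, against 2.27% in kept DMSO and 2.37% in kept selinexor cells. Mature neutrophils with little RNA, dying cells and an effect of selinexor on RNA content stay open as untested hypotheses.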
